A study of Homo sapiens with 30 samples.

How the data were processed

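RNA from 30 cultures of LX2, an established line of activated human hepatic stellate cells, was profiled by 3′ tag sequencing with a QuantSeq kit, per the labels' protocols. Such libraries give reads near the polyadenylated end of a transcript, so a level reflects the number of transcripts and not their length. The design crossed a fatty acid pretreatment (vehicle, oleic acid or docosahexaenoic acid, DHA) with betacellulin (BTC, a ligand of the ErbB receptor family) or its vehicle. The labels place the libraries in 6 groups of 5 and name 5 experiments, each with 1 library of every group. Groups are written as pretreatment and treatment, so DHA+BTC is DHA followed by BTC and Veh+Veh had neither, and the number after a group is the experiment.

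The deposited file held 1 table of CPM values (counts scaled to a common library total) for 61597 genes, and the authors had scaled each library to a sum of 1000000. Reads were aligned with STAR 2.5.3a and counted per gene with HTSeq 0.6.0, per the submitters' processing notes. The genome build and the annotation release were not given in the sources used here, so no coordinates are printed, and whether the counting used strand was not given either. Genes that overlap, antisense genes and near-identical copies can therefore share reads. Genes were named from their Ensembl identifiers with a table of symbols, which matched 61444 of them (99.8%).

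CPM values in a library were whole multiples of the value of 1 read. The reads recovered from those steps were whole, within 0.01 read, for 100% of the values in every library. Library totals ran from 1245182 to 9490142 reads with a median of 3683035, and the 3 shallowest libraries were DHA+BTC 5, DHA+Veh 5 and DHA+BTC 4. A count of 0 allows a level of up to 3 reads, which was 2.41 CPM in the smallest library and 0.316 CPM in the largest. Such floors cover counting error only, because PCR copies without molecular identifiers are not independent molecules.

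The main test was limma 3.58.1 in R 4.3.3, with a mean-dependent prior (trend), on log2(CPM + 1), for the 15137 genes at 1 CPM or more in at least 5 libraries. Of these, 13901 had a symbol. All 30 libraries entered 1 fit with the group and the experiment as terms. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no minimum fold. Differences are on the log2(CPM + 1) scale, which understates the change of genes near the floor, and folds are on the same scale. Intervals are 95% intervals from the limma fit. Every adjusted p of a gene comes from limma unless another tool is named.

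The experiment was a term of the fit because the labels give it as a characteristic of its own and because each experiment holds every group. The pairing was checked in the data before calls were compared. Deviations from the group means correlated in all 75 pairs of libraries from the same experiment, from 0.119 upward with a median of 0.507, against a median of -0.169 between experiments. Of the 30 libraries, 28 correlated best with their own experiment. The first principal component held 42.6% of the variance, and 93.1% of that lay between experiments. The numbers of genes called fell steeply without the block, and those numbers stand beside each result. Whether the experiments were separate cell passages was not given in the sources used here, so p-values measure the spread between these cultures of 1 line.

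The comparisons, the rule for named genes, the gene lists and the first set of alternatives were fixed before the data were examined. The comparisons were BTC against its vehicle after each pretreatment, each fatty acid against vehicle with and without BTC, the averages of these, DHA against oleic acid, and the interactions. The averaged comparisons were the main ones. They take the libraries with and without BTC of an experiment as independent given the experiment term. If a fatty acid response is shared within an experiment, their p-values may be too small and their counts too high. Named genes were the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean of at least 5 CPM in a group compared and the same direction in at least 4 of 5 experiments. Where fewer than 5 genes passed, those with the 5 smallest p-values were eligible. For each gene list described, up to 4 members with the smallest p-values were eligible, and EGFR, ERBB2, ERBB3, ERBB4, BTC, ACTA2, COL1A1, COL1A2, COL3A1, TGFB1, TGFB2, TIMP1 and MKI67 were eligible everywhere. The text prints only part of this pool. ERBB4 and BTC did not reach the minimum level for testing.

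There were 23 gene lists with 472 entries, of which 471 were found and 404 tested. They covered collagens and matrix, stellate activation and contractile genes, stellate quiescence, TGF-beta ligands and targets, matrix proteases and inhibitors, integrins, ErbB receptors and ligands, ERK-induced and feedback genes, cell cycle, cholesterol synthesis and uptake, cholesterol efflux and LXR targets, fatty acid synthesis and desaturation, fatty acid oxidation and PPAR targets, lipid droplet and triglyceride, NRF2 and antioxidant, unfolded protein and amino acid stress, inflammatory cytokines and NF-kB, interferon-induced, hypoxia and glycolysis, and markers of hepatocytes, epithelial cells and cholangiocytes, endothelial cells, and leukocytes and macrophages. Each list with at least 5 tested members was compared with all other genes by camera in limma with a preset correlation of 0.01. This left 21 lists, since 0 hepatocyte genes and 4 endothelial genes were tested. Their p-values were adjusted over the 21 lists. Members were also counted over all genes and adjusted over the list alone.

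The procedure was tested on simulated data, with counts drawn for the 15137 genes and 50 genes changed at each of 4 folds. For BTC averaged over the 3 pretreatments, 32%, 60%, 82% and 90% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold were recovered. For DHA averaged over BTC the shares were 18%, 58%, 76% and 82%, and for BTC without fatty acid 4%, 26%, 50% and 70%. For the interaction of DHA and BTC they were 0%, 4%, 30% and 48%. Unchanged genes called in these 4 simulations numbered 4, 11, 3 and 2. All 20 simulated lists changed 1.5-fold were recovered and 0 of 20 unchanged lists were called. Genes were drawn independently of each other in these simulations, so they could not show false list calls that come from correlation between genes.

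That first set of alternatives was pseudocounts of 0.5 and 5, no filter or a filter at 5 CPM, median-of-ratios scaling, quantile normalization, no replicate block, only the libraries of the groups compared, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each experiment and each library in turn. Thinning every library to the 1245182 reads of the shallowest, and leaving out the 3 shallowest libraries, were added after the data were seen. DESeq2 gave no adjusted p for 881 genes in the averaged DHA comparison. No pair of libraries within a group was a duplicate: over 60 pairs the chi-square per degree of freedom was 14.2 to 124.5 for genes with at least 20 reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.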

Results

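LX2 cells, a line of activated human hepatic stellate cells (the cells that lay down scar matrix in liver fibrosis), were exposed to a fatty acid and then to betacellulin (BTC), and their polyadenylated RNA was counted per gene. Oleic acid has 18 carbons and 1 double bond (ω9). Docosahexaenoic acid (DHA) has 22 carbons and 6 double bonds (ω3). Each was given at 50 µM on 20 µM albumin in 2 cycles of 48 h, and a protocol field gives 96 h for the fatty acid. BTC followed at 20 ng/ml in medium with 1% serum for 72 h. There were 6 groups of 5 libraries, 1 of each group in each of 5 experiments, with 1245182 to 9490142 reads per library. The comparisons asked what each fatty acid changed, whether the fatty acids differed, what BTC changed, and whether a fatty acid altered the response to BTC.

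DHA changed the expression of many genes, averaged over the presence of BTC. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 7.62 ± 5.61 CPM without fatty acid to 229.9 ± 187 CPM with DHA (SD, n = 10 in each), a log2 difference of 4.76 ± 0.32 (SE; 27.2-fold; adjusted p = 2.36e-11). CXCL8, the neutrophil-attracting chemokine interleukin 8, rose from 6.78 ± 5.84 to 200.7 ± 237 CPM (log2 difference 4.00 ± 0.46; adjusted p = 9.33e-07). The interstitial collagenase MMP1 rose from 127 ± 129 to 672 ± 419 CPM (log2 difference 2.81 ± 0.27; adjusted p = 9.49e-08). Among the largest falls was VGLL2, a transcriptional cofactor (log2 difference -2.21 ± 0.31; adjusted p = 2.61e-05). All 4 genes moved the same way in 5 of 5 experiments. Other large rises were those of CSF3 (log2 difference 3.73), the protease inhibitor TFPI2 (3.22), STC1 (2.81) and IL24 (2.65). Other large falls were those of CPA4 (-2.16), the receptor tyrosine kinase KIT (-2.06), RARRES2 (-2.05), MATN2 (-2.01), MSTN (-1.96), NPPB (-1.95) and APLN (-1.93), with adjusted p-values of 1.48e-05 to 0.00205.

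In total 1621 of 15137 genes were called for DHA averaged over BTC, of which 352 rose and 1269 fell, and 1144 of them had the same sign in 5 experiments. The 10 DHA libraries came from 5 experiments but entered the fit as independent, so the limma p-values may be too small and the count too high. The balance of rises and falls varied with the processing. Median-of-ratios scaling gave 528 rises and 753 falls, and quantile normalization 520 and 661. The tools edgeR and DESeq2, which change the test as well as the scaling, gave 454 and 496, and 636 and 734. The median of all genes moved from -0.13 on the CPM scale to -0.05 with median-of-ratios scaling and -0.00183 with quantile normalization, a shift smaller than every change of a called gene printed here. Without the experiment as a block 104 genes were called, 49 rises and 55 falls. DHA libraries had fewer reads than libraries without fatty acid (3028129 ± 1074169 against 4515158 ± 1933237, SD, n = 10; exact sign-flip permutation p = 0.0156, adjusted p = 0.109 over 35 tests), and 575 genes (188 rises and 387 falls) were called without the 3 shallowest libraries. In the same pairs the 10 most abundant genes took 9.56% of reads with DHA against 8.00% (higher in 8 of 10, exact sign-flip permutation p = 0.0117, adjusted p = 0.102), ribosomal protein genes 12.7% against 11.4% (higher in 8 of 10, p = 0.0488, adjusted p = 0.194) and mitochondrial genes 2.43% against 2.90% (lower in 8 of 10, p = 0.0547, adjusted p = 0.194). The 10 pairs came from 5 experiments and were flipped as if independent, so the p-values of these library measures may be too small. Of the 67 called genes named for this comparison, 62 kept their call without the 3 shallowest libraries and 29 kept it without the block. The 38 that lost it without the block were CPA4, MATN2, MSTN, NPPB, APLN, ACTA2, TAGLN, CALD1, MYL9, COL1A1, COL1A2, COL3A1, SPARC, THBS1, CCN2, INHBA, TGFB2, TIMP1, PLAUR, ITGA2, TOP2A, MKI67, TPX2, DHCR7, ACACA, ACSL3, CPT1A, G0S2, SLC7A11, SQSTM1, DDIT3, ENO2, SLC2A3, ICAM1, CXCL12, PHLDA1, ERBB2 and KRT18, with adjusted p-values from 0.0524 (DHCR7) to 0.756 (COL1A1).

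**Figure D1:**
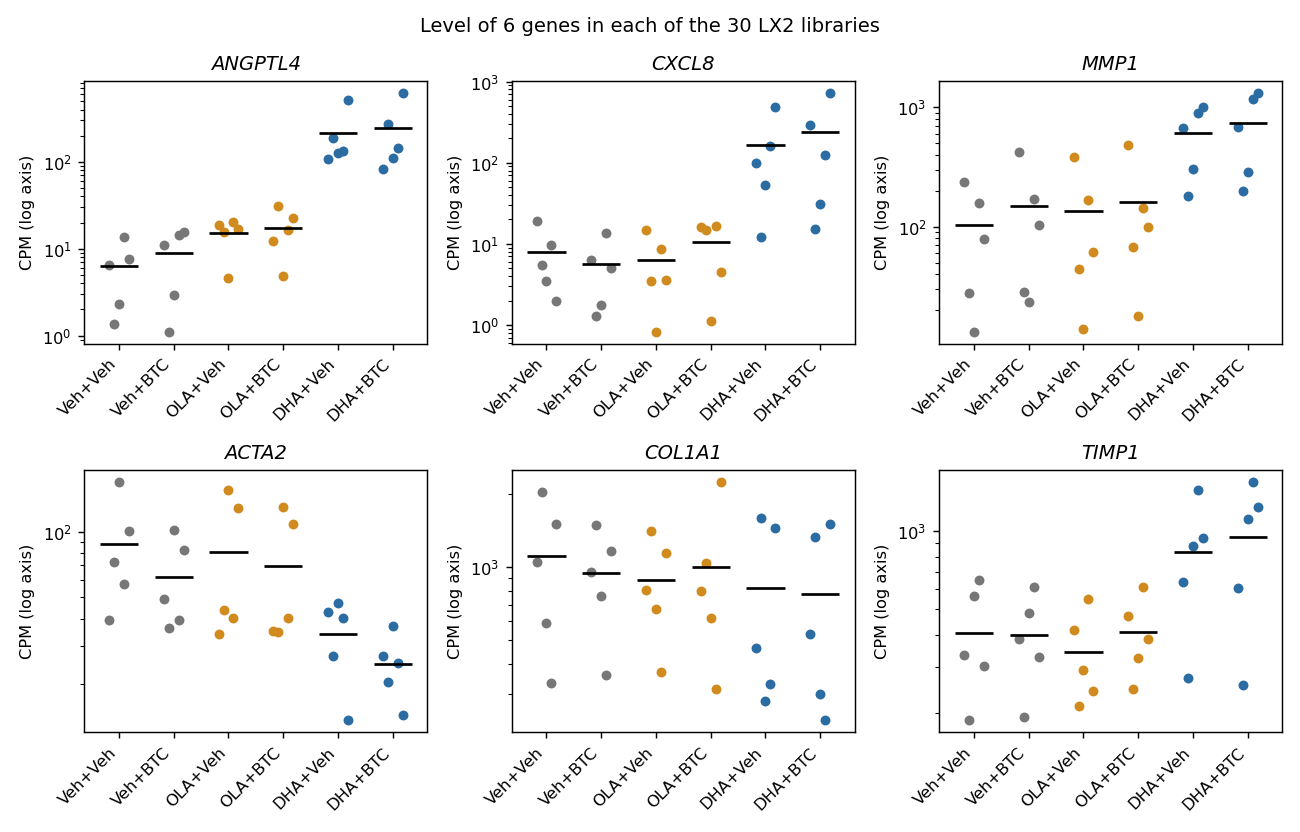
CPM on a log axis of 6 genes in each of the 30 libraries, by group, with points from left to right within a group for experiments 1 to 5 and bars for the group means. ANGPTL4, CXCL8, MMP1 and TIMP1 lay higher and ACTA2 lower on average in the DHA groups than in the groups without fatty acid, while the spread of COL1A1 within groups exceeded its difference between them.

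Inflammatory genes rose as a group with DHA (camera adjusted p = 5.61e-14). Of 30 tested cytokine and NF-kB genes, 13 rose and 2 fell, and 15 rose and 2 fell when adjusted over the list alone. The chemokines CXCL1 and CXCL3 rose by log2 differences of 3.07 and 3.05, and the adhesion molecule ICAM1 by 1.42, each in 5 of 5 experiments. IL1B, which encodes interleukin 1 beta, rose by 2.85. The homeostatic chemokine CXCL12 fell by 1.12 in 5 of 5 experiments (adjusted p = 1.63e-06). Interferon-induced genes did not pass the test (camera adjusted p = 0.418, with 0 rises and 1 fall by limma among 22 tested).

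Matrix-degrading proteases and their inhibitors also rose as a list (camera adjusted p = 0.000742), with 6 of 16 members risen and 2 fallen, and 6 risen and 3 fallen when adjusted over the list alone. MMP3, a stromelysin, rose by a log2 difference of 2.73 (SE 0.41), and the urokinase receptor PLAUR rose by 1.37, a call that ended without the 3 shallowest libraries (adjusted p = 0.0624). TIMP1, an inhibitor of these proteases, rose in the same samples, from 403 ± 166 to 895 ± 455 CPM (log2 difference 1.05 ± 0.16; adjusted p = 4.96e-05). Of 15 integrins, 3 rose and 1 fell (camera adjusted p = 0.00491; 4 and 1 when adjusted over the list alone). ITGA2, which pairs into a collagen receptor, rose by 1.70, ITGA5 rose by 0.94, and ITGB4 fell by 0.99. The integrin list did not pass without experiment 2 (camera adjusted p = 0.061).

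Contractile and activation genes of stellate cells fell with DHA (camera adjusted p = 5.09e-06). Of 17 tested, 0 rose and 10 fell by limma, and 1 rose and 10 fell when adjusted over the list alone. ACTA2, the smooth muscle actin used as a marker of activated stellate cells, fell from 74.8 ± 41.3 to 29.5 ± 11.8 CPM (log2 difference -1.25 ± 0.24; adjusted p = 0.000608; 5 of 5 experiments). TAGLN, CALD1 and MYL9, which encode actin- or myosin-associated proteins, fell by 1.21, 1.13 and 1.07. Stellate quiescence genes did not pass (camera adjusted p = 0.9; 0 of 11 called by limma, and 0 rises and 3 falls when adjusted over the list alone).

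The list of 30 collagen and matrix genes did not pass the test as a whole with DHA (camera adjusted p = 0.195; 4 rose and 10 fell, or 5 and 13 when adjusted over the list alone). COL1A2 fell by 1.51 (SE 0.30; adjusted p = 0.00105), and COL3A1 by 0.71 (SE 0.19; adjusted p = 0.0148). The matrix genes SPARC, LOXL1 and THBS1 fell by 0.92, 0.96 and 1.41. COL1A1 was at 1028 ± 551 CPM without fatty acid and 802 ± 585 with DHA (log2 difference -0.53, 95% interval -0.86 to -0.21; adjusted p = 0.0282; 4 of 5 experiments). Its call ended when any 1 of these libraries was left out: Veh+Veh 1, DHA+Veh 1, Veh+Veh 2, Veh+BTC 3, DHA+Veh 3, DHA+BTC 3 and DHA+BTC 4 (adjusted p = 0.0515 to 0.0699), or without experiments 1, 3 or 4 (0.156, 0.205 and 0.0777), and it was not reached with no filter (0.0737), with median-of-ratios scaling (0.15), edgeR (0.178) or DESeq2 (0.159). The COL3A1 call ended without the 3 shallowest libraries (adjusted p = 0.229) and without experiments 3 (0.0943) or 5 (0.109).

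TGF-beta ligands and targets went both ways (camera adjusted p = 0.0887; 3 rose and 2 fell of 21, both over all genes and adjusted over the list alone). CCN2, a matricellular protein induced by TGF-beta, fell by 1.68, and the ligand TGFB2 fell by 1.15 (SE 0.25; adjusted p = 0.00296, or 0.0521 without experiment 3). The cytokine IL11 rose by 1.69 and the activin subunit INHBA by 1.35. TGFB1 differed by 0.30 (95% interval -0.18 to 0.79; adjusted p = 0.456).

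Cholesterol synthesis and uptake genes fell together with DHA (camera adjusted p = 1.33e-15). Of 25 tested members, 0 rose and 17 fell by limma, and 0 rose and 23 fell when adjusted over the list alone. MVK, DHCR7 and ACAT2, which encode enzymes of the sterol pathway, fell by 1.29, 1.16 and 0.95 in 5 of 5 experiments. Fatty acid synthesis and desaturation genes fell as well (camera adjusted p = 0.000303), with 1 of 21 risen and 8 fallen, and 1 and 14 when adjusted over the list alone. SCD, the stearoyl-CoA desaturase, fell by 1.31 (SE 0.20; adjusted p = 4.96e-05), ACSL3 fell by 1.00 and ACACA by 0.66. The ACSL3 call ended without the 3 shallowest libraries (adjusted p = 0.0637).

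Fatty acid oxidation and PPAR target genes did not pass as a list (camera adjusted p = 0.0646; 4 of 24 rose and 2 fell, or 5 and 5 when adjusted over the list alone). Its median was -0.18 while its mean was 0.18 and the test pointed up. Beside ANGPTL4, the lipid droplet coat gene PLIN2 rose by 1.55 and CPT1A, the carnitine palmitoyltransferase of fatty acid import into mitochondria, by 0.71, whereas UCP2 fell by 1.18. Lipid droplet and triglyceride genes did not pass (camera adjusted p = 0.083; 3 of 13 rose and 2 fell, or 3 and 3 when adjusted over the list alone), with a median of -0.00364 and a test pointing up. G0S2, an inhibitor of triglyceride lipase, rose by 2.22 (adjusted p = 0.00232, or 0.0558 without the 3 shallowest libraries). Cholesterol efflux and LXR target genes did not pass (camera adjusted p = 0.676; 0 of 10 rose and 2 fell, or 2 and 2 when adjusted over the list alone). Their median was 0.07, their mean -0.15 and the test pointed up, and MYLIP fell by 1.44.

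Hypoxia and glycolysis genes rose with the smallest camera p of the 21 lists (adjusted p = 5.16e-22). Of 21 members, 12 rose and 0 fell by limma, and 16 rose and 0 fell when adjusted over the list alone. BNIP3, a mitophagy receptor, rose from 35.1 ± 10.8 to 88.7 ± 20.3 CPM (log2 difference 1.35 ± 0.15; adjusted p = 5.33e-07). The glycolytic enzyme genes PGK1 and ENO2 and the glucose transporter SLC2A3 rose by 0.99, 0.92 and 1.12.

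NRF2 and antioxidant genes rose (camera adjusted p = 2.73e-06; 5 of 21 rose and 1 fell, or 7 and 1 when adjusted over the list alone). HMOX1, the heme oxygenase, rose by 1.20, the cystine transporter SLC7A11 by 1.21 and SQSTM1 by 1.00. Unfolded protein and amino acid stress genes rose (camera adjusted p = 4.69e-05; 4 of 20 rose and 0 fell by limma, and as many when adjusted over the list alone), among them DDIT4 by 2.38 and DDIT3 by 1.05. ERK-induced and feedback genes rose (camera adjusted p = 3.56e-06; 4 of 23 rose and 0 fell by limma, and as many when adjusted over the list alone), among them IER3 by 1.78 and PHLDA1 by 1.04.

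Cell cycle genes fell (camera adjusted p = 1.39e-12). Of 32 tested, 0 rose and 19 fell by limma, and 0 rose and 23 fell when adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, fell by 1.24 (SE 0.17), TPX2 by 0.82, and the proliferation marker MKI67 by 0.85 (SE 0.16; adjusted p = 0.000513), from 169 ± 134 to 119 ± 124 CPM. All 11 lists called with DHA also passed camera with an estimated correlation (adjusted p = 0.000469 to 0.0369).

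Of the receptors through which BTC acts, EGFR did not pass the test with DHA and ERBB2 passed narrowly. EGFR was at 30.1 ± 16.9 CPM without fatty acid and 37.1 ± 24.1 with DHA (log2 difference 0.10, 95% interval -0.27 to 0.46; adjusted p = 0.794). ERBB2 fell from 38.8 ± 11.5 to 27.0 ± 8.74 CPM (log2 difference -0.52, 95% interval -0.84 to -0.19; adjusted p = 0.0327). The ERBB2 call ended when any 1 of DHA+Veh 1, Veh+BTC 3, DHA+Veh 3, DHA+BTC 3, Veh+Veh 4, DHA+BTC 4, Veh+Veh 5, Veh+BTC 5, DHA+Veh 5 and DHA+BTC 5 was left out (adjusted p = 0.05 to 0.0849), and with median-of-ratios scaling (adjusted p = 0.0993), quantile normalization (0.144), edgeR (0.138) and DESeq2 (0.105), at equal depth (0.074), without the 3 shallowest libraries (0.317), without experiments 3, 4 or 5 (0.211, 0.0828 and 0.196), with no filter (0.0536) and with only the groups compared (0.0968). ErbB receptors and ligands did not pass as a list (camera adjusted p = 0.0612; 2 of 10 rose and 1 fell, and as many when adjusted over the list alone). Among markers of other cell types, epithelial genes had a camera adjusted p of 0.956 (1 of 10 rose and 1, KRT18, fell by 0.97, with the same counts when adjusted over the list alone). Leukocyte genes had a camera adjusted p of 0.0887, with 0 of 8 called by limma and 0 when adjusted over the list alone.

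**Figure D2:**
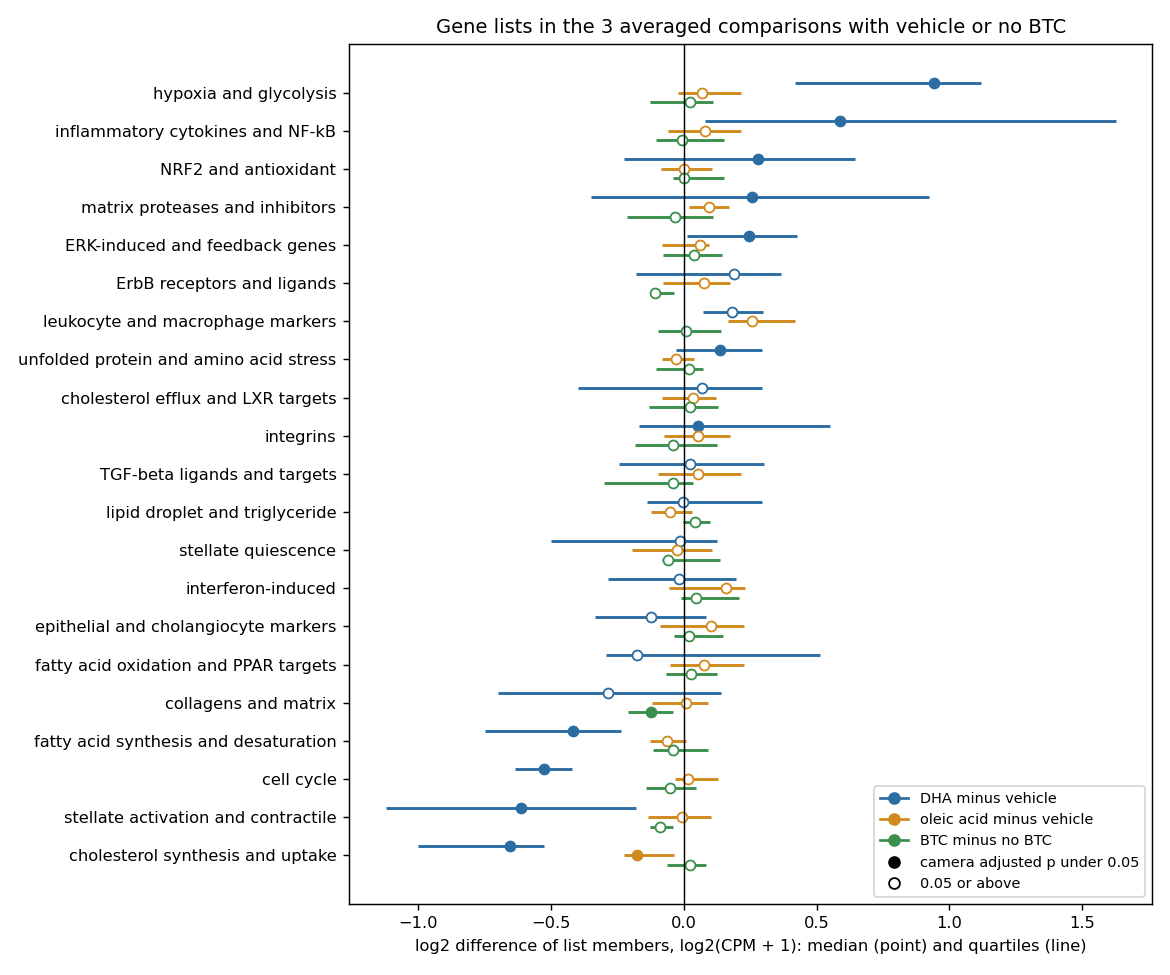
Median (points) and quartiles (lines) of the log2 differences of the members of 21 gene lists, for DHA minus vehicle, oleic acid minus vehicle and BTC minus no BTC, with filled points where camera gave an adjusted p under 0.05. The 11 lists called with DHA lay on both sides of 0, and 1 list each was called with oleic acid (cholesterol) and with BTC (collagens), neither of which passed with an estimated correlation (adjusted p = 0.847 and 0.883).

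The response to DHA was seen with and without BTC. Without BTC, 233 genes were called, 90 higher and 143 lower with DHA. With BTC, 537 were called, 164 higher and 373 lower. ANGPTL4 rose by log2 differences of 4.90 without and 4.62 with BTC, CXCL8 by 3.65 and 4.34, TFPI2 by 3.11 and 3.33, and STC1 by 2.53 and 3.08. MMP1 rose by 2.94 without BTC, where KIT fell by 2.42 and MATN2 by 2.10. With BTC, CSF3 rose by 3.98 and TIMP1 by 1.11, and RARRES2 fell by 2.21, ADRA1B by 2.20, SERPINB9 by 2.16 and TGFB2 by 1.76. The call sets shared 70 rises and 78 falls, where independent sets of these sizes would share 0.975 and 3.52. Both sets came from 1 fit with 1 spread per gene and a downward median of all genes (-0.14 without and -0.141 with BTC). Sharing above those numbers can therefore arise without a common response, and the overlap is no test of one. Whether the DHA response differed with BTC is tested by the interaction, which called 0 genes.

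These counts of 5 against 5 libraries were unstable. Without the block 1 gene was called in each. Without BTC, leaving out Veh+Veh 3, DHA+Veh 3, Veh+Veh 4, DHA+Veh 4, Veh+Veh 5 or DHA+Veh 5 gave 107, 102, 119, 135, 68 and 70 genes. With BTC, leaving out DHA+BTC 2, Veh+BTC 3, DHA+BTC 3, DHA+BTC 4, Veh+BTC 5 or DHA+BTC 5 gave 1101, 354, 344, 348, 205 and 179 genes. In that comparison edgeR gave 270, of which 170 were higher and 100 lower with DHA, the reverse of the balance by limma. A fit of only the groups compared gave 9, which kept 4 of the 10 genes named with BTC. Without the block ANGPTL4 alone of the genes named kept its call. Without BTC, the KIT call also ended without experiment 4 (adjusted p = 0.0591) and that of MATN2 without experiment 3 (0.0832). With BTC, the calls of ADRA1B (0.0546), CSF3 (0.0536) and TIMP1 (0.143) ended without the 3 shallowest libraries, those of TGFB2 (0.0702), RARRES2 (0.0673) and CSF3 (0.0661) without experiment 3, and that of TIMP1 without experiment 5 (0.0514). Median-of-ratios scaling gave 114 rises and 82 falls without BTC, and 226 and 223 with it.

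DHA and oleic acid were compared at the same 50 µM and over the same times, and differed in 1719 genes, of which 363 were higher and 1356 lower with DHA. Libraries with and without BTC of an experiment again entered as independent, so these p-values may be too small and the count too high. ANGPTL4 was higher with DHA by a log2 difference of 3.57 (95% interval 2.92 to 4.23; adjusted p = 3.88e-08; 5 of 5 experiments), at 229.9 ± 187 CPM against 16.3 ± 7.90 with oleic acid. CXCL8 differed by 3.79 (95% interval 2.86 to 4.72), with 8.47 ± 6.55 CPM under oleic acid. MMP1 differed by 2.63 (2.07 to 3.19), CSF3 by 3.97 (2.77 to 5.17), TFPI2 by 3.20 (2.59 to 3.81), STC1 by 2.56 (1.97 to 3.15) and ITGA2 by 1.67 (1.18 to 2.16). Lower with DHA were CPA4 (log2 difference -2.39, -3.11 to -1.68), MATN2 (-2.26, -2.82 to -1.71), the oxytocin receptor OXTR (-1.99, -2.56 to -1.42), COL1A2 (-1.60, -2.20 to -0.99), ACTA2 (-1.16, -1.64 to -0.68) and CALD1 (-1.16, -1.44 to -0.89).

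Of the gene lists, 12 differed between the fatty acids. Higher with DHA were hypoxia and glycolysis (camera adjusted p = 3.84e-21; 12 of 21 higher, 0 lower by limma), inflammatory genes (2.48e-13; 14 of 30 higher, 2 lower), NRF2 (6.72e-07; 5 of 21 higher, 0 lower by limma), ERK-induced genes (1.85e-06; 5 of 23, 0 lower), unfolded protein stress (3.57e-06; 4 of 20, 0 lower), matrix proteases (0.00162; 5 of 16, 2 lower), integrins (0.00528; 3 of 15, 1 lower) and lipid droplet genes (0.0172; 3 of 13, 2 lower). Adjusted over the list alone, 15, 16, 6, 6, 4, 6, 4 and 4 members of these lists were higher and 0, 4, 1, 0, 0, 5, 1 and 3 lower by limma, in the same order. Examples were BNIP3 (1.20), SLC7A11 (1.29), SQSTM1 (0.93), DDIT4 (2.40), TIMP1 (1.11), PLIN2 (1.07) and G0S2 (1.88). Lower with DHA were cell cycle genes (2.48e-13; 0 of 32 higher, 22 lower by limma), cholesterol synthesis (1.39e-09; 0 of 25 higher, 16 lower), stellate activation genes (2.76e-05; 0 of 17 higher, 9 lower) and fatty acid synthesis (0.00528; 1 of 21 higher, 7 lower). Adjusted over the list alone, 25, 17, 12 and 8 members of these were lower and 0, 0, 1 and 1 higher by limma. Examples were TOP2A (-1.33), MKI67 (-0.97), HMGCS1 (-1.19) and SCD (-1.18). All 12 passed with an estimated correlation (adjusted p = 0.000316 to 0.0433), but the lipid droplet list did not pass without the 3 shallowest libraries (camera adjusted p = 0.202) or without experiment 5 (0.18). G0S2 did not pass without those libraries (adjusted p = 0.133) or without experiments 3 (0.0986) or 5 (0.0684).

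Some genes were not told apart between the fatty acids. COL1A1 differed by -0.40 (95% interval -0.73 to -0.07; adjusted p = 0.0988), ERBB2 by -0.42 (-0.74 to -0.09; adjusted p = 0.0837) and EGFR by 0.22 (-0.14 to 0.59; adjusted p = 0.456). COL1A1 passed without OLA+BTC 2 (adjusted p = 0.0437) and ERBB2 without DHA+Veh 2 (adjusted p = 0.0351). Both passed without experiment 2 (adjusted p = 0.036 and 0.0305). The collagen and matrix list had a camera adjusted p of 0.494. Without the block, 68 genes were called between the fatty acids, and 10 of the 24 called genes named here kept their call. The 14 that lost it were CPA4, OXTR, COL1A2, ACTA2, CALD1, TIMP1, MKI67, TOP2A, HMGCS1, PLIN2, G0S2, SLC7A11, SQSTM1 and ITGA2 (adjusted p = 0.0701 to 0.613). With the block, edgeR called 965 (484 higher and 481 lower with DHA). Without the 3 shallowest libraries limma called 537 (182 higher and 355 lower). Median-of-ratios scaling gave 515 higher and 752 lower with DHA. The 10 most abundant genes took 9.56% of reads with DHA and 7.95% with oleic acid, higher with DHA in 10 of 10 pairs (exact sign-flip permutation p = 0.00195, the smallest these pairs can give; adjusted p = 0.0682 over 35 tests). In the same pairs reads per library were 3028129 ± 1074169 with DHA against 4200426 ± 818122 (lower in 8 of 10, exact sign-flip permutation p = 0.0234, adjusted p = 0.136), genes at 1 CPM or more 12740 against 13240 (lower in 9 of 10, p = 0.00977, adjusted p = 0.102) and mitochondrial ribosomal RNA 0.294% against 0.356% of reads (lower in 8 of 10, p = 0.0117, adjusted p = 0.102).

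**Figure D3:**
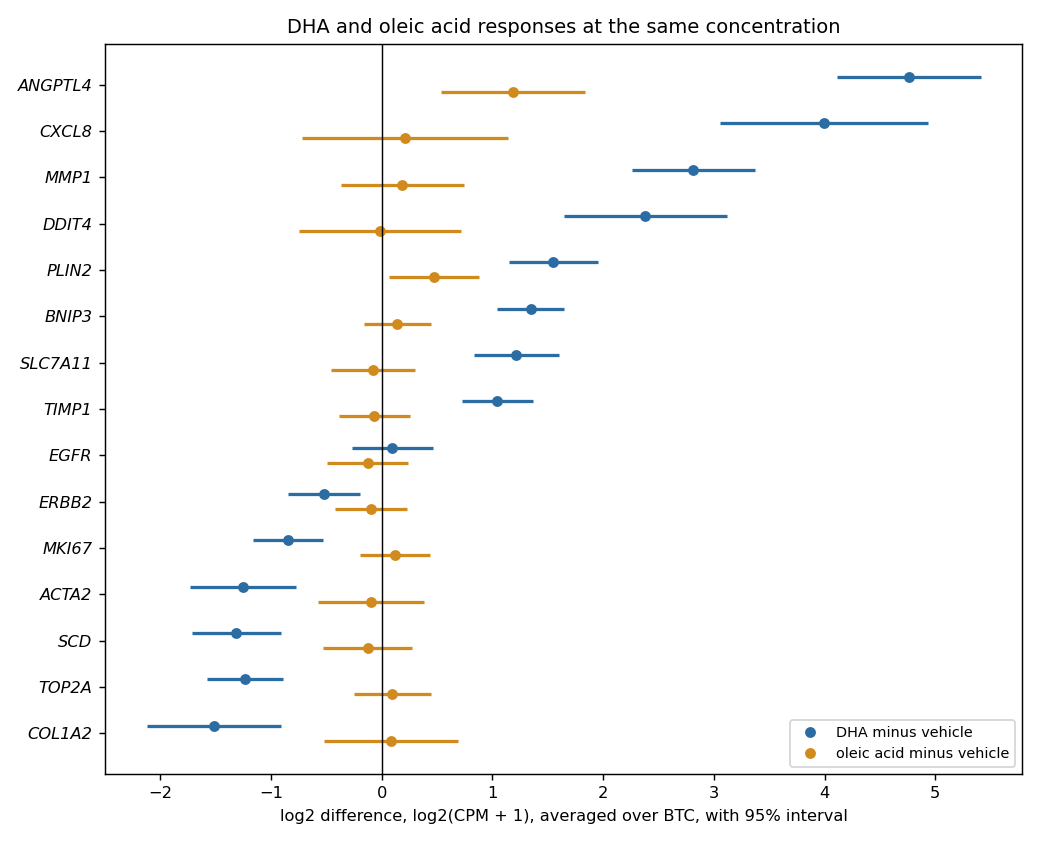
Log2 differences from vehicle, averaged over BTC, of 15 genes with DHA and with oleic acid, as points with 95% intervals. The intervals of EGFR overlapped, and those of ANGPTL4, CXCL8 and MMP1 lay apart.

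Oleic acid gave small differences from vehicle. Limma called 0 of 15137 genes averaged over BTC (302 at an unadjusted p under 0.05, where 757 are due by chance), and edgeR and DESeq2 also called 0. ANGPTL4 was at 16.3 ± 7.90 CPM with oleic acid and 7.62 ± 5.61 without (log2 difference 1.19, 95% interval 0.54 to 1.84; adjusted p = 1; higher in 5 of 5 experiments). The monoamine oxidase gene MAOA differed by 0.89, PLIN2 by 0.48 and ZNF584-DT by -0.84, each with an adjusted p of 1. Cholesterol synthesis and uptake genes were lower as a list (camera adjusted p = 3.43e-05, median -0.18), but with an estimated correlation the adjusted p = 0.847. In it 0 of 25 members were called by limma and 1 was when adjusted over the list alone. TMEM97, HSD17B7 and DHCR7 differed by -0.43, -0.78 and -0.38. The list call also ended without experiment 2 (adjusted p = 0.179).

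Without BTC limma called 0 genes with oleic acid (468 at an unadjusted p under 0.05; edgeR and DESeq2 0), and with BTC also 0 (1044 at an unadjusted p under 0.05; edgeR and DESeq2 0). The smallest p-values belonged to genes such as EIF3A (log2 difference 1.00), SPTLC3 (-1.04) and DCLRE1C (0.81) without BTC, and SCOC-AS1 (1.33), DMRTA1 (-1.18) and MTRES1 (0.98) with it. None passed the correction. Cholesterol genes were lower without BTC (camera adjusted p = 0.0228; adjusted p = 0.966 with an estimated correlation). Leukocyte genes had a camera adjusted p of 0.258 with oleic acid, and 7 of the 8 tested had their highest level of the 30 libraries in OLA+BTC 2. Without that library limma still called 0 genes with oleic acid, averaged or with BTC.

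Averaged over the 3 pretreatments, single genes did not pass the test with BTC. Limma called 0 of 15137 genes (609 at an unadjusted p under 0.05, 757 due by chance; edgeR and DESeq2 0). CCN2 was lower with BTC by a log2 difference of -0.55 (95% interval -0.86 to -0.23; 5 of 5 experiments; adjusted p = 0.994). GAB1, which encodes an adaptor of receptor tyrosine kinases, differed by -0.64 (-0.99 to -0.28), and WDR53, CCDC190 and SLC7A7 differed by -0.73, -0.59 and 0.82, all with an adjusted p of 0.994. Collagen and matrix genes were lower as a list (camera adjusted p = 0.0131, median -0.12), with 0 of 30 members called by limma and 0 when adjusted over the list alone. With an estimated correlation the adjusted p = 0.883, without the block it was 0.252, and without experiments 3 or 5 it was 0.154 and 0.231. COL1A2 differed by -0.50 (95% interval -0.996 to -0.01), SPARC by -0.39 and FN1 by -0.21.

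Genes downstream of the ErbB receptors did not move together with BTC. ERK-induced and feedback genes had a camera adjusted p of 0.614, with 0 of 23 called by limma and 0 when adjusted over the list alone, and DUSP6 and JUNB differed by -0.42 (95% interval -0.92 to 0.08) and -0.28 (-0.57 to 0.01). Cell cycle genes had a camera adjusted p of 0.748 (0 of 32 called by limma), ErbB receptors and ligands 0.614 and stellate activation genes 0.53. ACTA2 differed by -0.33 (95% interval -0.72 to 0.06).

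Within single pretreatments limma also called 0 genes with BTC. Without fatty acid, mitochondrial ribosomal RNA (0.45% of reads with BTC against 0.302%) and RN7SL1 (22.4 against 2.65 CPM) were each higher with BTC in 5 of 5 experiments (exact sign-flip permutation p = 0.0625, the smallest these pairs can give, and adjusted p = 0.194 over 35 tests). Veh+BTC 3 carried much of both: without experiment 3 the mean difference went from 0.148 to 0.0691 percentage points for mitochondrial ribosomal RNA and from 19.8 to 4.65 CPM for RN7SL1. The counts at an unadjusted p under 0.05 were 1539 without fatty acid, 299 after oleic acid and 629 after DHA, edgeR called 0 in each, and DESeq2 called 1 gene without fatty acid, 1 after oleic acid and 0 after DHA. Without fatty acid the smallest adjusted p was 0.445, shared by SEL1L3 (log2 difference -1.06), MTRES1 (-1.09), WDR53 (-1.44), EIF3A (0.99) and ARHGEF10L (-0.82). After oleic acid the vault RNA VTRNA1-1 differed by -1.61 (adjusted p = 0.956; DESeq2 adjusted p = 0.014), RPP14 by 1.05 and MRPL2 by -0.81. After DHA, HYAL3 differed by 1.48, SERPINB9 by -1.43 and COL1A2 by -0.87, with an adjusted p of 1.

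No gene passed the test of whether a fatty acid altered the response to BTC. The interaction of DHA and BTC called 0 genes by limma (527 at an unadjusted p under 0.05; edgeR and DESeq2 0), as did that of oleic acid and BTC (1279 at an unadjusted p under 0.05; edgeR and DESeq2 0). TGFB2 had interaction terms of -1.21 with DHA (95% interval -2.24 to -0.17; adjusted p = 0.983) and -1.61 with oleic acid (-2.65 to -0.58; adjusted p = 0.584). Its BTC differences were 0.66 without fatty acid and -0.95 after oleic acid. Other terms with small p-values were those of SCOC-AS1 (1.92) and ADAMTS7 (-1.90) with DHA, and of RNU4ATAC (-2.73) and VTRNA1-1 (-2.12) with oleic acid. Of the lists, ErbB receptors and ligands had the smallest camera adjusted p in the DHA interaction (0.116), and shared the smallest with inflammatory genes in the oleic acid interaction (0.263). In the simulation of the DHA interaction, 48% of genes changed 4-fold, 30% of those changed 3-fold and 4% of those changed 2-fold were recovered. Many interactions of single genes would therefore be missed here.

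The 50 genes with the smallest p-values for BTC, after oleic acid and after DHA, were followed in fatty acid comparisons that share no library with them. Limma called 0 genes with BTC in either (edgeR 0, and DESeq2 1 after oleic acid). In 8 such tests 0 passed by camera, and the smallest adjusted p was 0.0886, for the 23 genes higher with BTC after DHA, whose median with oleic acid in the presence of BTC was -0.16. An unadjusted p under 0.05 was reached by 3 of the 8, and these 3 passed the correction with 100 genes, with median-of-ratios scaling and without experiment 4.

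Across genes, the DHA and oleic acid differences without BTC correlated with r = 0.249, where genes are not independent replicates. Both use the same Veh+Veh libraries, and unchanged groups simulated against those controls gave r = 0.501 (0.481 to 0.522 in 100 simulations). Genes were drawn independently there, so that range leaves out the spread from correlated genes. The SD of r over the 5 experiments was 0.15. The covariance was 0.0331 against 0.0493 simulated, a difference of -0.0162. With the controls split the median r was -0.0203 (-0.117 to 0.0861 over 20 splits), and from fully separate libraries r was -0.0501 and -0.162.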

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

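The tests of explanations and the counts of other splits given here were all worded only after the results they bear on had been seen, and part of the marker genes used below was chosen after their values were seen. The search for libraries far from the rest of their group was planned.

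In 108 groups of 5 values, 1 library was looked for whose gap to the nearest other exceeded 0.71 of the group's range. The values were library measures as given here, RN7SL1 among them, and genes with printed levels, searched on log2(CPM + 1). Such a library was found in 5 groups, and chance gives about 1 in 20, so their number is no more than chance gives. Mitochondrial ribosomal RNA took 0.8% of reads in Veh+BTC 3 against 0.3% to 0.415% in the other Veh+BTC libraries. The same library held RN7SL1, a signal recognition particle RNA, at 83.3 CPM against 4.57 to 14.0 CPM. RN7SL1 also stood apart in OLA+BTC 2 (14.5 CPM against 0.608 to 3.93). ANGPTL4 was at 4.54 CPM in OLA+Veh 3 against 15.6 to 20.3 in the others of its group (a gap of 0.814 of the range on the log2 scale). ERBB2 was at 46.0 CPM in OLA+BTC 5 against 35.5 to 36.7.

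More genes fell than rose with DHA, with 21.7% of the calls upward. After every library was thinned to equal depth 24.2% were upward, which argues against the lower number of reads in itself as the whole cause, but without the 3 shallowest libraries 32.7% were upward (188 rises and 387 falls), so a part tied to those libraries stays open. With median-of-ratios scaling 41.2% were upward, so part of the excess of falls may come from the scaling of the deposited CPM values. With the scaling unchanged but without the experiment as a block, 47.1% were upward (49 rises and 55 falls). The share also varied with the number of genes called, at 38.6% of 233 for DHA without BTC and 30.5% of 537 with it. A higher share among fewer calls therefore cannot by itself be tied to the shallow libraries or the block. The scaling factors averaged 0.986 ± 0.233 in DHA+Veh and 0.949 ± 0.238 in DHA+BTC, against 1.06 ± 0.212 in Veh+Veh and 1.02 ± 0.164 in Veh+BTC (SD, n = 5). A wider fall in transcripts with DHA was not tested and stays open.

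Leukocyte genes stood out in OLA+BTC 2, where 7 of the 8 tested members of that list had their highest level of the 30 libraries. A response to oleic acid with BTC is argued against, since over these genes the other 4 libraries of the group lay at a median log2 difference of -0.41 from the libraries of other groups. Of 22 genes listed for red blood cells, B cells and intestine, 20 were detected and 18 had their highest level in OLA+BTC 2, which is in line with reads from other cells or another library. HBD was at 1594 CPM there against a median of 38.8 in the others, HBB at 263 against 3.44, ITGB2 at 1533 against 74.5 and IGKC at 157 against 5.60. Where such reads could come from was not tested. They were not confined to OLA+BTC 2. OLA+Veh 4 ranked next for FABP6 (46.88 CPM, against a median of 1.856 outside OLA+BTC 2), CLCA1 and MUC2. OLA+BTC 1 ranked next for IGKC (33.97 CPM) and IGHA1 (20.13 CPM), and other markers were next highest in further libraries. ITGB2 was also high in DHA+BTC 5 (424 CPM) and Veh+Veh 3 (310.5 CPM). DHA+BTC 5 held the highest CD68 of the 30 libraries (44.97 CPM, against 10.81 in OLA+BTC 2). It ranked next after OLA+BTC 2 for CSF1R, TYROBP, HLA-DRA and FABP4 (130.9 CPM, against a median of 8.923 outside OLA+BTC 2). CD74 was at 0 CPM in DHA+BTC 5, and PTPRC, LYZ and FCER1G were highest after OLA+BTC 2 in other libraries. All 30 libraries, these included, stayed in the main fit.

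Hypoxia and glycolysis genes rose together with DHA, with a median log2 difference of 0.94. With median-of-ratios scaling the median was 1.06 and without the 3 shallowest libraries 0.824, and each argues against that technical source as the cause. A hypothesis left open is that DHA may raise these genes in the cells themselves. The labels give 40000 cells per well for every library. Oxygen level and cell density at harvest were not given in the sources used here.

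Other splits of the same libraries were drawn to see whether chance can be excluded, 100 for each comparison with the real split among them. For DHA averaged over BTC 1 split, the real one, called as many as 1621 genes, and the highest other called 945. For DHA against oleic acid 1 split called as many as 1719, with 0 genes in the highest other (limma). For DHA without BTC 1 split called as many as 233, and the highest other called 3. Most of these splits mix experiments, so splits that only swap groups within experiments, as the pairing asks, were also counted. For DHA averaged over BTC 1 of 100 such splits (drawn from 512), the real one, called as many, with 1348 in the highest other. For DHA against oleic acid it was 1 of 100 (drawn from 512), with 182 in the highest other. DHA without BTC has 16 such splits (1 as large, highest other 0 by limma) and DHA with BTC 16 (3 as large, highest other 1131), too few for a share under 0.05. In the averaged comparisons the pairs with and without BTC of an experiment were swapped separately. Swaps of whole experiments would be as few as 16, so chance is excluded for the averaged comparisons only if those pairs are independent. For DHA with BTC 5 splits of 100 called as many as 537, with 1131 in the highest other, so chance cannot be excluded there. That share lies at the threshold itself, and which 100 of the 126 possible splits are drawn decides its side: another draw fell just under it. In that highest split the groups were swapped in experiments 1, 3 and 5.

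For the comparisons with 0 calls by limma all 100 splits called as many or more, which any split must, so this count says nothing about chance there. The highest of the other splits called 599 genes for BTC without fatty acid, 0 for BTC after oleic acid, 107 for BTC after DHA, 18 for oleic acid without BTC, 948 for oleic acid with BTC, 1 for BTC averaged, 503 for oleic acid averaged, 2 for the DHA interaction and 949 for the oleic acid interaction.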

How the results depend on the processing

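The fits without the 3 shallowest libraries, at equal depth and with separate libraries for the correlation were chosen only after the results were seen. The other alternatives were planned.

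Among the called genes named for DHA averaged over BTC, 65 of 67 kept their call with edgeR, DESeq2 and median-of-ratios scaling, 66 with quantile normalization and at equal depth, and 62 without the shallow libraries. Of 24 named between the fatty acids, 24 kept it with each of these tools and scalings. No called gene named changed direction. EGFR with DHA, not called at 0.10, ranged from -0.0327 to 0.392 with an experiment or library left out, and was -0.0123 without experiment 2.

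The replicate block moved counts and list tests. Without the block the counts were 1 for DHA without BTC, 1 for DHA with BTC, 104 for DHA averaged and 68 for DHA against oleic acid, and the collagen list with BTC had an adjusted p of 0.252. That fit by its construction leaves the spread between experiments in the error. Without it, fatty acid oxidation and PPAR targets passed with DHA (adjusted p = 0.0397) and leukocyte and macrophage markers with oleic acid (0.0129). Of the genes named, 38 of 67 lost their call with DHA averaged, 14 of 24 between the fatty acids, 6 of 7 without BTC and 9 of 10 with it. Apart from these and the medians below, the block changed no other call of an averaged comparison, list or named gene.

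Counts also moved with other settings. DHA without BTC (233) gave 101 with no filter, 139 at equal depth, 149 without the shallow libraries, and 38 to 273 with an experiment or a library left out. DHA with BTC (537) gave 342 with no filter, 9 with only the groups compared, 270 by edgeR, 79 without the shallow libraries, and 126 to 1101 in the same way. DHA averaged (1621) gave 1001 with only the groups compared, 950 by edgeR, 575 without the shallow libraries, and 763 to 2071. DHA against oleic acid (1719) gave 965 by edgeR, 537 without the shallow libraries, and 601 to 2102. Fewer libraries give fewer degrees of freedom, and otherwise the cause was not tested. DESeq2 called 1 gene for BTC without fatty acid and 1 for BTC after oleic acid.

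Of the lists, collagens with BTC had an adjusted p of 0.883 with an estimated correlation and 0.00511 to 0.231 with an experiment left out. Cholesterol genes with oleic acid had 0.847, and 3.41e-09 to 0.179. Integrins with DHA ranged from 0.000718 to 0.061. Lipid droplet genes between the fatty acids had 0.202 without the shallow libraries, and 0.00663 to 0.18. Some lists not called passed with fewer libraries, and the cause was not tested. With DHA these were interferon genes without the shallow libraries (0.0322) or experiment 5 (0.015), ErbB genes without experiments 3 (0.037) or 4 (0.0191), TGF-beta genes without 5 (0.0485), and without 3 the PPAR (0.0148), lipid droplet (0.048) and leukocyte lists (0.0131). Leukocyte genes with oleic acid passed without 3 (0.000821) or 5 (0.0142), but not with an estimated correlation (adjusted p = 0.904), and pointed down without 2 (0.685), which leaves out OLA+BTC 2. Between the fatty acids PPAR targets passed without 2 (0.0404) and ErbB genes without 3 (0.0461) or 4 (0.0389), and so did ErbB genes in the DHA interaction without 3 (0.0379).

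Medians of the genes with the smallest p for BTC, in fatty acid comparisons, were unstable, and the cause was not tested. Genes higher with BTC after oleic acid (-0.118 in DHA with BTC) gave 0.00232 with 100 genes, 0.0041 without the block, 0.0452 with median-of-ratios scaling and -0.341 to 0.0562 with an experiment left out. In DHA without BTC (-0.0477) they gave 0.0882 with that scaling and -0.103 to 0.239. Genes lower with BTC after oleic acid (-0.296 in DHA with BTC) passed with 100 genes (-0.399), with that scaling (-0.281), and without experiments 2 and 4 (adjusted p = 0.0206 and 0.0496), and ranged from -0.479 to -0.159. In DHA without BTC (-0.123) they ranged from -0.277 to 0.172.

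Genes higher with BTC after DHA (-0.16 in oleic acid with BTC) gave 0.0118 without the block, passed with 100 genes (-0.16), with that scaling (-0.193) and without experiment 4 (adjusted p = 0.00169), and ranged from -0.25 to 0.0512. In oleic acid without BTC (0.193) they gave -0.0611 without the block, passed with 100 genes (0.208), with that scaling (0.229) and without experiment 4 (adjusted p = 0.00568), and ranged from -0.0487 to 0.316, with -0.00437 without experiment 1. Genes lower with BTC after DHA ranged from -0.0617 to 0.197 in oleic acid with BTC. In oleic acid without BTC (-0.0708) they gave 0.0235 with that scaling and -0.112 to 0.0432.

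The correlation of the DHA and oleic acid responses (0.249) became -0.0203 with the controls split and -0.0501 and -0.162 from separate libraries, since the shared controls no longer entered both. Depth limits genes near the floor, where 3 reads are 0.316 to 2.41 CPM.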

Other observations

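The test of a general rise of PPAR targets and the look at single experiments were chosen only after the results were seen. The test of oleic acid as a weaker form of DHA was worded before its result.

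The differences in single experiments correlated across genes at r from -0.344 to 0.549 for BTC without fatty acid, over the 10 pairs of experiments (median -0.0456, with 6 pairs below 0). The medians were -0.03 for BTC after oleic acid, -0.0155 for BTC after DHA and -0.0113 for oleic acid without BTC, each with 6 pairs below 0, and 0.108 for oleic acid with BTC, with 2 below 0. For DHA with BTC the range was -0.432 to 0.393 (median 0.0926), with 3 pairs below 0, and for DHA without BTC it was -0.0438 to 0.247 (median 0.157), with 1 pair below 0. Genes are not independent replicates, and a value near 0 is also what no response would give.

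ANGPTL4, PLIN2 and CPT1A are targets of PPAR receptors, and their rise with DHA might reflect a general rise of fatty acid oxidation and PPAR target genes. That would place most members of the list above the median change of all genes, but 10 of 24 were (41.7%), which argues against it.

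The cholesterol list was lower with oleic acid as with DHA under the preset correlation, and oleic acid could give a weaker form of the DHA response across all genes. From separate libraries the correlation across genes was -0.0501 and -0.162. Their spread over experiments was not taken, and the r with shared controls had an SD of 0.15 over experiments. The summed covariance from separate libraries was -0.0318 with an exact sign-flip permutation p of 0.0703 (1024 flips). A weaker form would need a covariance above 0, and these values do not separate it from 0. The bound set for that test, an r under 0.1, was too loose. The oleic acid differences repeated little between experiments (median r -0.0113 without BTC and 0.108 with it). A weak shared response would then also give an r near 0, so the hypothesis stays open.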
